A study of Mus musculus with 3 samples.

How the data were processed

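YY1 ChIP-seq was carried out on sorted cardiac progenitor cells at day 6 of embryoid body differentiation, with 2 ChIP samples and 1 input. The labels' protocols describe sonicated chromatin, an anti-YY1 antibody, Illumina library preparation with gel selection of fragments and sequencing on the Genome Analyzer. The ChIP samples were sorted independently, per the series design text; p-values computed here compare positions within these 2 lists and do not measure the spread between cultures.

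The deposited files are 1 interval list per ChIP sample, with chromosome, start, end, interval name and score. Per the file headers, the intervals are peaks called by the authors with MACS run in Galaxy. The MACS version and settings and the aligner are not given in the sources used here. The score of each interval is the MACS score as the authors deposited it; its formula is not given in the sources used here, so it was used within a list, to describe, rank and filter its intervals, and between the lists through ranks alone, in the rank correlation over shared intervals and in the choice of named intervals. Scores are discrete, since 83.6% of replicate 1 intervals and 95.1% of replicate 2 intervals had a score that another interval of the same list also had. Where a cut by score or the edge of a decile or quartile fell within a tie, the order of the list decided. Because there is a separate list for each sample, peaks were taken to have been called per sample. The design text states that the ChIP samples were examined against the input, and how the input entered the peak calling is not given in the sources used here. Interval names were numbered without a gap in both lists, and no interval overlapped another of its own list. A caller's score threshold and the number of reads both set how many intervals a list holds, so the list sizes cannot be read as numbers of binding sites. No values of the input were used here.

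The genome build is mm9, per the submitters' processing notes. The gene table used for reference belongs to GRCm38, and on 9 of 21 chromosomes the lists held intervals beyond the last GRCm38 gene. Coordinates were not carried between builds. The planned tests of promoters, of the YY1 sequence motif and of 22 gene lists therefore were not run, and the intervals are named by mm9 coordinates, counted from 1 on the premise that the files follow the BED convention of counting starts from 0.

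An interval was called shared when it overlapped an interval of the other list by at least 1 bp. The shared count was compared with 1000 random placements of the replicate 1 intervals on their own chromosome, with their widths kept, between the first and the last interval of either list on that chromosome; placed intervals could overlap each other. Assembly gaps and unmappable stretches were not left out of the placements, which lowers the overlap expected by chance. Shares are given with 95% exact (Clopper-Pearson) binomial intervals. Scores and widths were compared on the log2 scale with two-sided permutation tests (100000 permutations; 1000 for replicate 2), and the agreement of scores with Spearman's rho and 100000 permutations. Chromosome X was compared with the autosomes by Fisher's exact test. Ratios of densities have intervals from the exact binomial distribution of the counts, and stratified odds ratios are Mantel-Haenszel estimates. The rule for named intervals, fixed before the data were examined, was the 20 shared intervals with the lowest mean of their score ranks in both lists; 19 of them were also chosen when ranks were divided by the length of the list. Intervals outside that rule (the widest, the strongest unshared) were chosen after their values were seen.

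Alternatives fixed before the data were examined were an overlap of 50% of the shorter interval, midpoints within 500 bp, the 50% or the 25% of each list with the highest score, merging of intervals closer than 500 bp, and the autosomes alone. Further ones were added after seeing the data. The overlap test was tested on simulated data in which replicate 1 intervals were placed at random and a known share was moved onto replicate 2 intervals. With 40.5% of the 3691 intervals planted it recovered 40.0% above placement, with 4.53% planted it recovered 4.56%, and with none planted the permutation p was 0.692. The simulated positions were drawn by the same rule as the placements. The simulation therefore checks the computation and not whether random placement describes chance in these lists. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.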

Results

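Binding of YY1, a zinc-finger transcription factor that can activate or repress its targets, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in cardiac progenitor cells. The cells were derived from mouse embryonic stem cells grown for 6 days as embryoid bodies, aggregates in which the stem cells differentiate. Cells carrying a green fluorescent reporter driven by Nkx2-5, a homeodomain transcription factor of early heart cells, were then sorted. The series holds 2 YY1 ChIP samples from separate sorts and 1 input sample. The question was which places in the genome YY1 occupies in these cells. An interval list was analysed for each of the 2 ChIP samples, and the input was not analysed here. The comparison made was therefore between the 2 ChIP samples. Read totals were not used here, so the depth behind each interval is unknown, and all binomial intervals cover counting error only.

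The 2 samples differed widely in how many places were called. Replicate 1 held 3691 intervals and replicate 2 held 115109, which is 31.2 times as many. Together the intervals covered 335 kb in replicate 1 and 8736 kb in replicate 2. The intervals were narrow in both samples, with a median width of 83 bp in replicate 1 (interquartile range 60.5 to 101 bp) and 61 bp in replicate 2 (51 to 79 bp). These are widths of peak calls, and what sets them was not tested. Only 2.60% of replicate 1 intervals and 2.82% of replicate 2 intervals were wider than 200 bp. The peak score that MACS, the peak caller, gave each interval is the authors' value and ranks intervals within a list, a higher score being a stronger call; its levels were not compared between the lists. Its median was 77.3 in replicate 1 and 129 in replicate 2, and the lowest scores in the lists were 50.08 and 50.01. In replicate 2, 6 intervals scored above 3100, up to 3201.96, and 102 had the score of exactly 3100 and were not separated from each other.

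Many of the places called in replicate 1 were called again in replicate 2. Of the 3691 replicate 1 intervals, 1500 overlapped a replicate 2 interval by at least 1 bp. This is 40.6% (95% exact binomial interval 39.0 to 42.2%), and the other 2191 overlapped none. When the replicate 1 intervals were placed at random on their own chromosomes, 26.8 ± 5.22 (SD over 1000 placements) overlapped, or 0.726%, and no placement gave more than 45. The observed overlap was 56.0 times the mean of the placements (one-sided permutation test, p = 0.001, the smallest that 1000 placements can give). In the other direction, 1452 of the 115109 replicate 2 intervals, or 1.26% (1.20 to 1.33%), met a replicate 1 interval. When only the 3691 replicate 2 intervals with the highest scores were kept, 664 replicate 1 intervals were shared (18.0%, 16.8 to 19.3%), against 1.78 in random placements.

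The strongest intervals of replicate 1 were all found in replicate 2. All 13 replicate 1 intervals with a score of 1000 or more were shared (lower bound of the 95% exact binomial interval 75.3%). When the replicate 1 list was cut into deciles of score, 66.7% (61.6 to 71.5%) of the highest decile was shared and 26.2% (21.8 to 31.0%) of the lowest. Shared replicate 1 intervals had a median score of 85.8 and unshared ones of 75.1. The shared intervals had the higher scores (two-sided permutation test of the mean log2 score, p = 1e-05, the smallest that 100000 permutations can give). In replicate 2 the shared intervals also had the higher scores, with a median of 402 against 129 for the unshared. Of the 935 replicate 2 intervals with a score of 1000 or more, 266 were also called in replicate 1 (28.4%, 25.6 to 31.5%). Of the 116 replicate 2 intervals with a score of 3000 or more, 87 were also called in replicate 1 and 29 were not (95% exact binomial interval of the shared fraction 66.1 to 82.6%). The highest replicate 2 score was 3201.96 among the unshared intervals and 3171.31 among the shared ones.

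**Figure D1:**
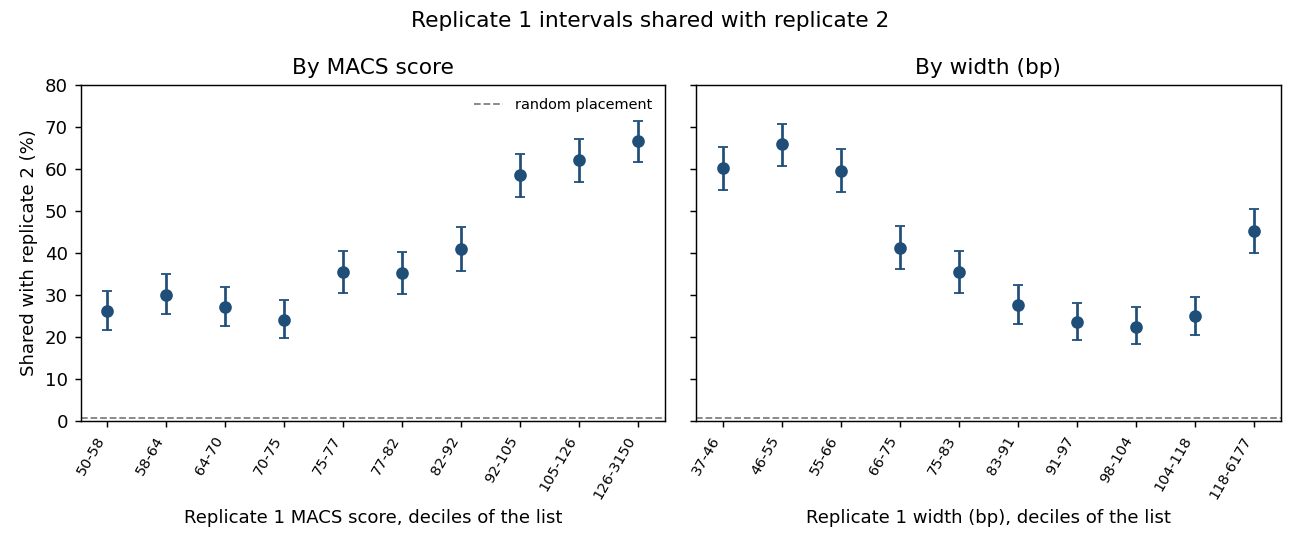
Share of replicate 1 intervals that overlap a replicate 2 interval (vertical axis, percent), by deciles of the replicate 1 list ordered by MACS score (left) or by width in bp (right). Points are shares, bars are 95% exact binomial intervals and the dashed line is the mean of 1000 random placements (0.726%). The share was 26.2% in the lowest and 66.7% in the highest score decile. It fell from 65.9% at widths of 46 to 55 bp to 22.5% at 98 to 104 bp and was 45.3% from 118 bp upward.

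The shared fraction also changed with the width of the replicate 1 interval. It was 60.3% (55.1 to 65.3%) for the narrowest decile, 37 to 46 bp wide, and 65.9% (60.8 to 70.7%) for the next, 46 to 55 bp wide. It was 22.5% (18.3 to 27.1%) at 98 to 104 bp and 45.3% (40.1 to 50.5%) in the widest decile, from 118 bp upward. Shared replicate 1 intervals had a median width of 70 bp and unshared ones of 89 bp, and the geometric mean width of the shared was 0.856 times that of the unshared (two-sided permutation test, p = 1e-05). In replicate 2 the order was the opposite, since shared intervals there had a median width of 98 bp and unshared ones of 61 bp, a ratio of geometric means of 1.76 (two-sided permutation test with 1000 permutations, p = 0.001, the smallest they can give).

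The 20 shared intervals with the best mean rank in both lists lay on 13 chromosomes. Coordinates are those of mm9, counted from 1, as called in replicate 1. The highest-ranked interval was on chromosome 17 from 31568400 to 31569408, with scores of 3149.52 in replicate 1 and 3100 in replicate 2 and widths of 1009 and 1059 bp. The next was on chromosome 18 from 48248006 to 48248112, which scored 222 in replicate 1 and 3171.31 in replicate 2. It ranked only 56 in replicate 1 and 3 in replicate 2. Its place rests on replicate 2, where each interval tied at 3100 took rank 57.5. This was the interval that was not chosen when ranks were divided by the length of the list. The interval on chromosome 19 from 32609959 to 32610255 scored 3100 in both samples. On chromosome 12, the interval from 15846611 to 15846975 scored 2606 in replicate 1, and on chromosome 17 that from 35008102 to 35008304 scored 2302. Replicate 1 scores between 1334 and 2135 belonged to intervals on chromosome 15 (99767010 to 99767512), chromosome 3 (68002839 to 68003478), chromosome 14 (121828495 to 121828751), chromosome 1 (14008778 to 14009265), chromosome 13 (45408631 to 45408886), chromosome 19 (34967831 to 34967990) and chromosome 18 (81861393 to 81861579). Those on chromosome 5 from 148525676 to 148526225 and on chromosome 11 from 112200679 to 112201138 scored 1284 and 1099.83. The other 6 scored 525 to 998 in replicate 1. They lay on chromosome 4 (129881137 to 129882070), chromosome 1 (40663223 to 40663809 and 181879734 to 181880107), chromosome 5 (133323328 to 133323761 and 8394712 to 8395075) and chromosome 2 (163712994 to 163713375). The interval on chromosome 18 that began at 48248006 was the only one of the 20 whose replicate 2 score was not exactly 3100, so the order of the other 19 follows replicate 1. These 20 were wider than the lists as a whole, with median widths of 378 bp in replicate 1 and 440 bp in replicate 2.

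The widest interval of replicate 2, on chromosome 4 from 129879365 to 129885970 (6606 bp), took in 11 separate replicate 1 intervals between 129880452 and 129885936, whose scores ranged from 66.3 to 998. Neighbouring intervals were close together more often than random positions in both lists. In replicate 1, 166 pairs of adjacent interval midpoints lay within 500 bp of each other, against a mean of 2.73 and a maximum of 8 in 100 random placements. In replicate 2 there were 5983 such pairs, against a mean of 2527 and a maximum of 2630.

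Scores of the shared intervals agreed only weakly between the samples. Each of the 1500 shared replicate 1 intervals was paired with the replicate 2 interval that it overlapped most. The pairs held 1450 distinct replicate 2 intervals. Some replicate 2 scores and widths thus entered several pairs, which the permutation tests do not take into account. Across these pairs, which are not independent replicates, Spearman's rho between the scores was 0.08 (two-sided permutation test, p = 0.00147). The relation lay in the strongest quartile of the pairs by replicate 1 score (115.38 to 3149.52), where rho was 0.45 (two-sided permutation test, p = 1e-05, 4e-05 after Benjamini-Hochberg adjustment over the 4 quartiles). In the other quartiles rho was -0.03, 0.01 and 0.01, with an adjusted p of 0.895 in each permutation test, and over those 1125 pairs together it was -0.03 (permutation p = 0.254). Widths agreed more closely, with a rho of 0.60 (two-sided permutation test, p = 1e-05), and the replicate 2 interval was the wider in 1315 pairs (87.7%).

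**Figure D2:**
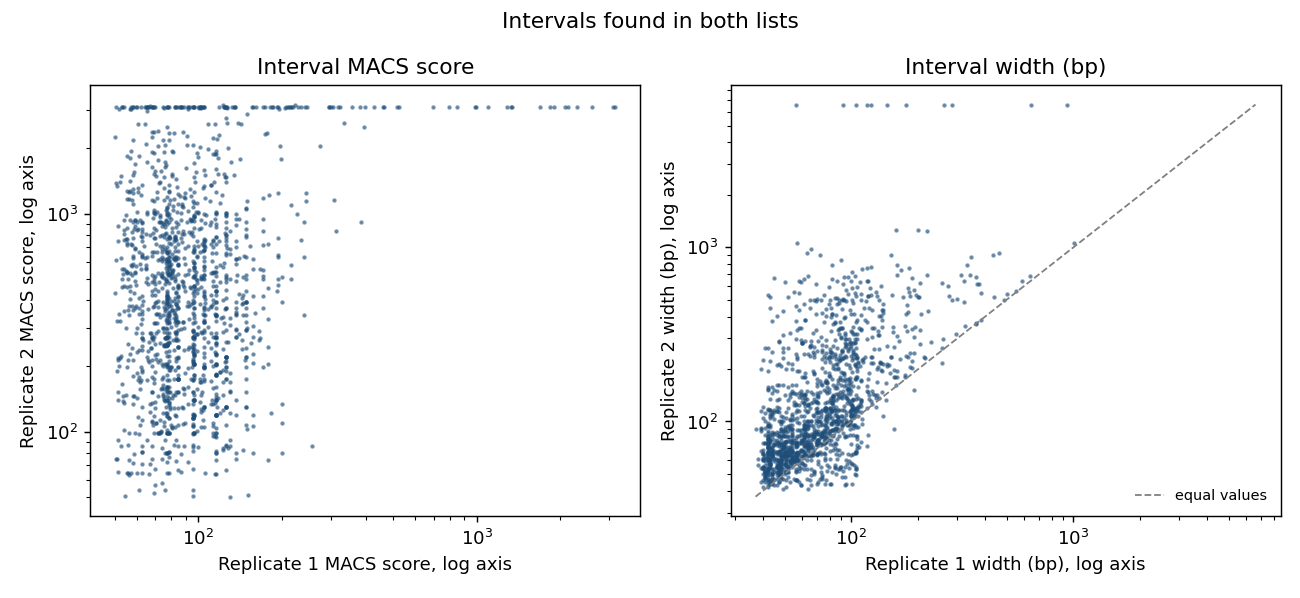
Score (left) and width in bp (right) of the 1500 replicate 1 intervals that overlap a replicate 2 interval, replicate 1 on the horizontal and replicate 2 on the vertical axis, all axes logarithmic. Each point is a pair and the dashed line in the width plot marks equal widths; 1315 pairs lie above it, and the row of points at the top of the score plot holds replicate 2 scores at or near 3100.

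Replicate 1 intervals on chromosome X were shared less often than those on the autosomes. On the 19 autosomes the shared fraction of replicate 1 intervals ranged from 34.8% on chromosome 6 to 48.1% on chromosome 19, and no difference among them was detected (permutation test with 10000 permutations of the shared intervals, p = 0.565). On chromosome X 31 of 181 replicate 1 intervals were shared, or 17.1% (95% exact binomial interval 11.9 to 23.4%), against 1459 of 3438 on the autosomes, or 42.4% (40.8 to 44.1%). The odds ratio was 0.280 (Fisher's exact test, two-sided, p = 1.86e-12). Replicate 2 held 26.9 intervals per Mb on chromosome X and 45.2 per Mb on the autosomes, a ratio of 0.596 (95% interval from counting error 0.578 to 0.614), where a chromosome's length was taken as the span between its first and last interval. For replicate 1 the densities were 1.11 and 1.42 per Mb, a ratio of 0.779 (0.667 to 0.905). On chromosome Y and the unplaced sequences, which held 1.95% of the replicate 1 intervals, 10 of 72 were shared (13.9%, 6.87 to 24.1%). The comparison of chromosome X with the autosomes, like those of shared with unshared intervals, was chosen after the values had been seen.

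**Figure D3:**
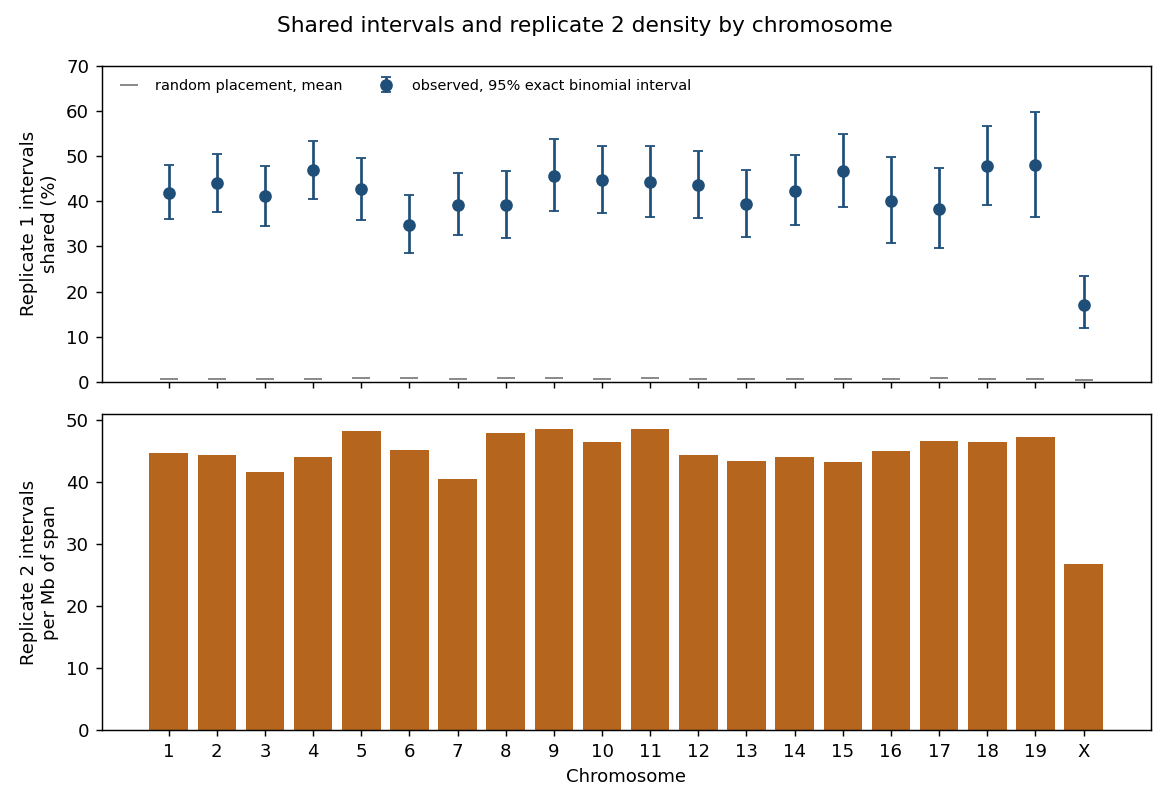
Share of replicate 1 intervals that overlap a replicate 2 interval (top, percent) and replicate 2 intervals per Mb of chromosome span (bottom), for each autosome and chromosome X. Points are shares with 95% exact binomial intervals and short grey lines are means of 1000 random placements; the autosomes lie between 34.8% and 48.1% and chromosome X at 17.1%, with 26.9 replicate 2 intervals per Mb.

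The 2191 replicate 1 intervals without an overlap lay beside replicate 2 intervals less often than random placement over whole chromosomes would put them. Of these, 116 (5.29%) had a replicate 2 interval within 1000 bp. In 1000 random placements this held for 7.94 ± 0.595% (SD) of the placed intervals that did not overlap a replicate 2 interval, a ratio of 0.667 (one-sided permutation test for fewer, p = 0.001, the smallest they can give). This test was not among the planned ones, and the opposite direction was computed too. The placements moved each interval on its own and so broke the clustering of replicate 1 intervals. The SD and p-value may therefore be too small. No placement near each interval was run here, so a local shortage of replicate 2 intervals was not separated. Scores of the 2191 unshared intervals reached 319 at most. The strongest were on chromosome 6 from 47689898 to 47690105 with a score of 319, chromosome 17 from 13744968 to 13746042 with 312, and chromosome 3 from 152472200 to 152472530 with 287. The widest interval of replicate 1, on chromosome 9 from 3000004 to 3006180 (6177 bp, score 149), was among the unshared.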

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

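The overlap of the 2 lists exceeded random placement under each of its 9 alternatives, by 10.05 to 374 times, the lowest with midpoints within 500 bp and the highest with replicate 2 cut to the size of replicate 1. The shared fraction of replicate 1, 40.6% as reported, was 46.1% for the 50% of each list with the highest score, 50.8% for the 25% with the highest score, 42.4% on the autosomes alone, 42.5% without replicate 1 intervals that had another within 10 kb, and 18.0% with replicate 2 cut to the size of replicate 1; the last fell because fewer replicate 2 intervals were left to meet, the autosomal value and that without near neighbours rose because the intervals left out were shared less often, and the cause of the changes with score was not tested. With the other 3 alternatives it stayed within its binomial interval. The weak positive rank correlation of scores, 0.08, kept its direction under 3 alternatives that used scores (0.08 to 0.20). It reversed to -0.034 without the quartile of pairs with the highest replicate 1 score, where the permutation p was 0.254, so it rests on that quartile. The alternative with widths gave 0.60, but it measures another quantity and does not bear on the scores. The lower odds of sharing on chromosome X (odds ratio 0.15 to 0.44 over 7 alternatives) and the higher score of shared replicate 1 intervals (8 alternatives) kept their direction and their side of the threshold. Ties at a cut by score were broken by list order. In replicate 1 this order put chromosome X after the autosomes, so its tied intervals were left out first. The alternatives without a cut by score gave odds ratios of 0.28 to 0.31 for chromosome X. The comparison of chromosome X and that of the scores of shared intervals with their alternatives, the placement within 100 kb, the removal of near neighbours, the equal list sizes, the widths, the autosomes alone for the scores and the removal of the strongest quartile were chosen after seeing the data. None of these 5 results could be recomputed without a replicate, because each compares the 2 lists; values of a single list are given per replicate. The alternatives planned for promoters, motifs and gene lists, and those for files of reads, were not run, since no mm9 annotation or sequence was used and the files hold intervals. Depth limits the comparison: without read counts, a place called in 1 list and missing from the other cannot be called unbound there.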

Other observations

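The tests of chance by broad chromosome stretches, of dense clusters, and of score and width composition were set before their results were seen; those of input enrichment and of read depth on chromosome X were chosen after, and the reading of the test of replicate 2 density was revised after its result was seen.

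The overlap of the 2 lists, 1500 intervals, was 56.0 times that of random placement. A common preference for the same broad stretches of the chromosomes is argued against as its whole cause, since the overlap was still 49.2 times that of placements within 100 kb of each interval (one-sided permutation test, p = 0.001). Dense clusters are argued against too, since it was 60.3 times chance without replicate 1 intervals that had another within 10 kb. Places that pile up reads in the input as well, such as repeats or copy-number gains, stay open. On chromosome Y and unplaced sequences 13.9% of the replicate 1 intervals were shared, less than on the autosomes. The share was still above random placement in the sets with the most intervals. It was 18.75% against 0.375% on Y_random, and 4.35% against 0.396% on Un_random, from 1 shared interval. Some smaller sets had no shared interval. These sequences held few intervals and the input was not analysed here, so the shares do not decide. A common preference for stretches much narrower than 100 kb, for reasons other than YY1, was not tested and stays open too. Occupancy by YY1 at the same sites in both sorts is the biological explanation the design offers, and it stays open as a hypothesis, since the motif was not tested.

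The low shared fraction on chromosome X, 17.1% against 42.4% on the autosomes, went with a lower density of replicate 2 intervals there. Whether that density accounts for it stays open: the fold over random placement on chromosome X was 0.767 times that on the autosomes (95% interval 0.519 to 1.09). This decides little, because a ratio of 1 is expected only if sharing scales with density, and whether it does is not known. The fold rose from 56.0 to 374 when replicate 2 was cut by score, but that cut changed density and score at once. A lower read depth on chromosome X, which fewer X copies in the cells would give, stays open as well. The pooled replicate 1 intervals were sparser there, with 0.779 times the autosomal density (95% interval 0.667 to 0.905). Fewer YY1 sites or other sequence content would also make them sparser. Neither these nor the number of X copies was tested. The shared replicate 1 intervals had a ratio of 0.314 (0.213 to 0.448) and the unshared ones of 1.12 (0.943 to 1.32). This goes against fewer calls of every kind but does not decide, since low sharing itself moves intervals from the first class to the second. Differences in score or width are argued against as the cause, since the odds ratio was 0.264 (0.172 to 0.405) within deciles of score and quartiles of width.

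Replicate 1 intervals at or below the median width of 83 bp were shared in 52.3% of cases (50.01 to 54.6%) and wider ones in 28.7% (26.6 to 30.8%), an odds ratio of 2.73 (2.38 to 3.12). This split hides the higher share in the widest decile, from 118 bp upward, where 45.3% (40.1 to 50.5%) were shared. The higher scores of the narrow intervals are argued against as the whole cause, since the odds ratio was 2.07 (1.78 to 2.40) within deciles of score, though its decrease from 2.73 leaves room for a part. A different share of chromosomes X and Y and unplaced sequences is argued against by an odds ratio of 2.69 (2.34 to 3.09) on the autosomes alone. No biological explanation was tested. Score and width were negatively related across replicate 1 intervals (Spearman's rho -0.34) and positively across replicate 2 intervals (0.14), intervals not being independent replicates.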
